A study of Rattus norvegicus with 6 samples.

How the data were processed

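Total RNA of the livers of 6 male rats, 5 weeks old at purchase, was labelled with Cy3 and hybridised to Agilent one-colour rat expression arrays, 3 of vehicle-treated and 3 of tBA-treated animals, per the labels. The intensity values of each array were made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, and version 10.7 is given in the submitters' processing notes; the software subtracts the local background and writes a processed signal per spot. The deposited series table holds, per array, a linear ratio: dividing the processed signals by the table gave 1 divisor per array, between 570.0 and 639.5, close to that array's 75th percentile. Column medians of this table were 0.102, 0.102 and 0.0994 for vehicle replicates 1 to 3 and 0.0981, 0.0949 and 0.0952 for tBA replicates 1 to 3, so it is a linear scale without centring per gene, and higher values mean more signal. The array annotation uses the rn4 genome, per the file headers.

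The log2 of the processed signal minus each array's 75th percentile over 61657 probes was the measure. Control spots were left out, and 3 to 16 outlier-marked spots per array were treated as missing. A probe was tested when it was well above background on all arrays of at least 1 group, which left 37647 probes. Differences, tBA minus vehicle, were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the Benjamini-Hochberg adjusted p under 0.05 over the probes tested. With 3 arrays against 3 the smallest exact two-sided permutation p is 0.1. A gene took the value of its probe with the highest mean signal over the 6 arrays; of 5497 genes with several tested probes, 1634 had probes of opposite sign. Where all arrays of a group were not well above background, a bound was given: the mean of the bright group against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

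Probes were named through their accession in a table of RefSeq genes of the GRCr8 assembly. Of 29123 probes with an NM accession 27348 matched, of 3940 with an XM accession 75, of 41 with an NR accession 37, and none of the 252 with an XR accession or the 6746 with an Ensembl transcript. In all, 27460 probes were named with 15284 symbols, and no coordinates were used because the builds differ.

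Gene lists for pathways and cell types were fixed before the data were examined and tested with camera, with a preset inter-gene correlation of 0.01, over 39 lists of at least 3 tested genes. Members were also adjusted over the list alone. The genes named are the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap, with places left over filled by unadjusted p; a fixed sentinel list; and up to 4 members of each list described, by smallest p. Genes known only by an accession or locus number were passed over. Among the genes so named, 2 are not reported here as single genes or among the named genes followed through the alternatives; they stay in each test, list and count of calls.

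Alternatives were normexp background correction with an offset of 50, quantile and median normalization, the percentile over detected probes, the authors' table, other filters and a floor on dim signals, an intensity trend in eBayes, slide as a fixed or random block, slide 1 alone, a replicate block, and leaving out each array in turn. Normexp was run on the median signal in place of the planned mean signal, which was not used here. The within-slide test of the gene lists was chosen after seeing the data. Slide and scan day coincide, and neither can be told apart from the other. The scripts were tested on simulated data: over 37629 probes and 10 datasets, each with 200 changed probes, the tBA against vehicle fit called 49.9% of 2-fold changes, 87.2% of 4-fold and 93.3% of 8-fold, and 5.31% of all calls were false. For the lists, a shift of 0.5 in 1 list of 11091 simulated independent genes was called in 10 of 10 datasets, with 0 calls in 380 tests of the other lists. Real genes were not independent: in the lists that passed, the estimated correlation ran from 0.019 to 0.50. The simulated rate of false calls therefore does not carry over to them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables read with numpy 2.4.6 and pandas 2.3.3.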

Results

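Liver RNA of male Sprague-Dawley rats, an outbred laboratory stock, was measured on 6 one-colour microarrays. Of the 6 rats, 3 received vehicle and 3 received tert-butyl alcohol (tBA), a branched alcohol used as a solvent, at 1000 mg/kg/day. The labels disagreed on 2 points: the sample labels gave water as the vehicle where the treatment protocol gave corn oil, and the series gave 28 days of dosing where the treatment protocol gave 9 weeks. Between 61.5% and 66.9% of the 61657 probes were well above background on each array, and no spot was saturated. Arrays of the same group correlated at 0.989 or higher across probes, and arrays of different groups at 0.984 to 0.988. The first principal component, with 38.6% of the variance, placed the 3 vehicle arrays between -37.3 and -36.9 and the tBA arrays at 20.3, 52.1 and 38.7. Slide 1 held the 3 vehicle arrays and tBA replicate 1, and slide 2 held tBA replicates 2 and 3, so a within-slide comparison was 3 arrays against 1. The number of arrays limited the precision.

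The comparison of tBA with vehicle asked which liver transcripts differed after repeated dosing. Of the named genes, 4 fell and 1 rose. Rtn4ip1, which encodes a mitochondrial protein, fell by 2.81 on the log2 scale (SE 0.21, adjusted p = 0.0161). Socs2, an inhibitor of growth hormone signalling that the hormone itself induces, fell by 1.85 (SE 0.17, adjusted p = 0.0306). Nuf2, a kinetochore component of dividing cells, was well above background on the 3 vehicle arrays and on none of the tBA arrays, and was at least 2.91-fold lower in the processed signal against the background limit of each array (adjusted p = 0.00624). Mal, a membrane raft protein, was likewise not well above background in the tBA group and was at least 1.33-fold lower by the same measure (adjusted p = 0.0174). Grin2c, a subunit of the NMDA glutamate receptor, rose by 1.36 (SE 0.10, adjusted p = 0.0174). In each of these 5 genes the 3 tBA values lay outside the vehicle range, which the naming rule asked for. Each of the 5 had only 1 tested probe, so no other probe could check the call. Leaving out tBA replicate 2 ended the 5 calls, at adjusted p of 0.0733 for Rtn4ip1, 0.155 for Socs2, 0.0620 for Nuf2, 0.116 for Mal and 0.112 for Grin2c. The calls of Rtn4ip1, Socs2, Mal and Grin2c also ended without vehicle replicate 1 (adjusted p = 0.0627 to 0.117), vehicle replicate 3 (0.0757 to 0.115) or tBA replicate 3 (0.0620 to 0.0949), those of Socs2 and Mal without vehicle replicate 2 (0.132 and 0.0902) and that of Grin2c without tBA replicate 1 (0.0595). The replicate block ended the 5 calls (0.109 to 0.204), no filter on dim probes those of Rtn4ip1, Socs2, Mal and Grin2c (0.0537 to 0.0938), the filter to probes above background on all 6 arrays those of Rtn4ip1, Socs2 and Grin2c (0.0811 to 0.118) and left Nuf2 and Mal untested, the intensity trend that of Mal (0.126) and the mean of all probes that of Socs2 (0.0557). With slide as a fixed block, where the estimate sets tBA replicate 1 alone against the vehicle arrays, Socs2 was at -2.21 (adjusted p = 0.0383, and 0.108 within slide 1) and Rtn4ip1, Nuf2, Mal and Grin2c at -3.15, -1.68, -1.46 and 1.38, with adjusted p of 0.0572 to 0.153. The 2 fold bounds do not hold under other treatments of dim signals: with normexp background correction Nuf2 was at -0.43 (adjusted p = 0.105) and Mal at -0.15 (adjusted p = 0.444), and with 1 floor for all arrays Nuf2 was at -1.50 (adjusted p = 0.00239) and Mal at -0.37 (adjusted p = 0.173).

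Across all probes, 43 of 37647 tested passed an adjusted p of 0.05 in limma, 26 higher and 17 lower with tBA. Only 9 of the 43 could be named, and 34, of which 24 were higher, carried no name here. Among 11094 genes, each read from its brightest probe, 5 passed. Another 4 genes, Spata31d1, Wdfy3, Tbc1d14 and Duox1, had a probe that passed which was not their brightest, and they were singled out after their values were seen. At an unadjusted p under 0.05 the same test gave 1674 genes, 848 higher and 826 lower. Groups did not overlap in 24.1% of genes, against 10% by chance. The number of passing probes was 6 without tBA replicate 2, 14 without tBA replicate 3, 22 without vehicle replicate 1 and 25 without vehicle replicate 3. With slide as a fixed block, which leaves tBA replicate 1 as the treated arm, 20 probes, 8 higher and 12 lower, and 2 genes passed, of which 6 probes and 1 gene were among the 43 and the 5, and within slide 1 limma passed 0 probes, with 2956 at an unadjusted p under 0.05.

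The remaining places of the fixed naming rule went to genes ranked by unadjusted p, none of which passed. On the higher side were Abcc3, a basolateral exporter of conjugates, at 1.94 (SE 0.25, adjusted p = 0.0859), Dusp13b at 1.48 (SE 0.16, adjusted p = 0.0513), Npas2 at 1.36, Aoc1 at 1.21, Zfp949 at 1.02, Slc12a3 at 1.01, Prodh, which starts proline breakdown, at 1.00, Slc4a11 at 0.81 and Dmbx1 at 0.80, all as log2 differences of tBA minus vehicle. On the lower side were Jun, an immediate early transcription factor, at -1.67 (SE 0.19, adjusted p = 0.0604), Bhlhe40 at -1.45, Pcdh7 at -1.15 and Foxn2 at -0.70. Ccdc77 and C15h8orf74 were not well above background on the tBA arrays and were at least 4.06-fold and 2.03-fold lower in the processed signal, with adjusted p of 0.0515 and 0.0728. These bounds do not hold with normexp background correction, where Ccdc77 was at -0.63 and C15h8orf74 at -0.39, nor for C15h8orf74 with 1 floor for all arrays, at -0.98. Under normexp Foxn2 was at -0.19, Pcdh7 at -0.53, Aoc1 at 0.61, Dusp13b at 0.90, Slc4a11 at 0.52 and Dmbx1 at 0.48, and Pcdh7 was at -1.79 by the mean of its probes.

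**Figure D1:**
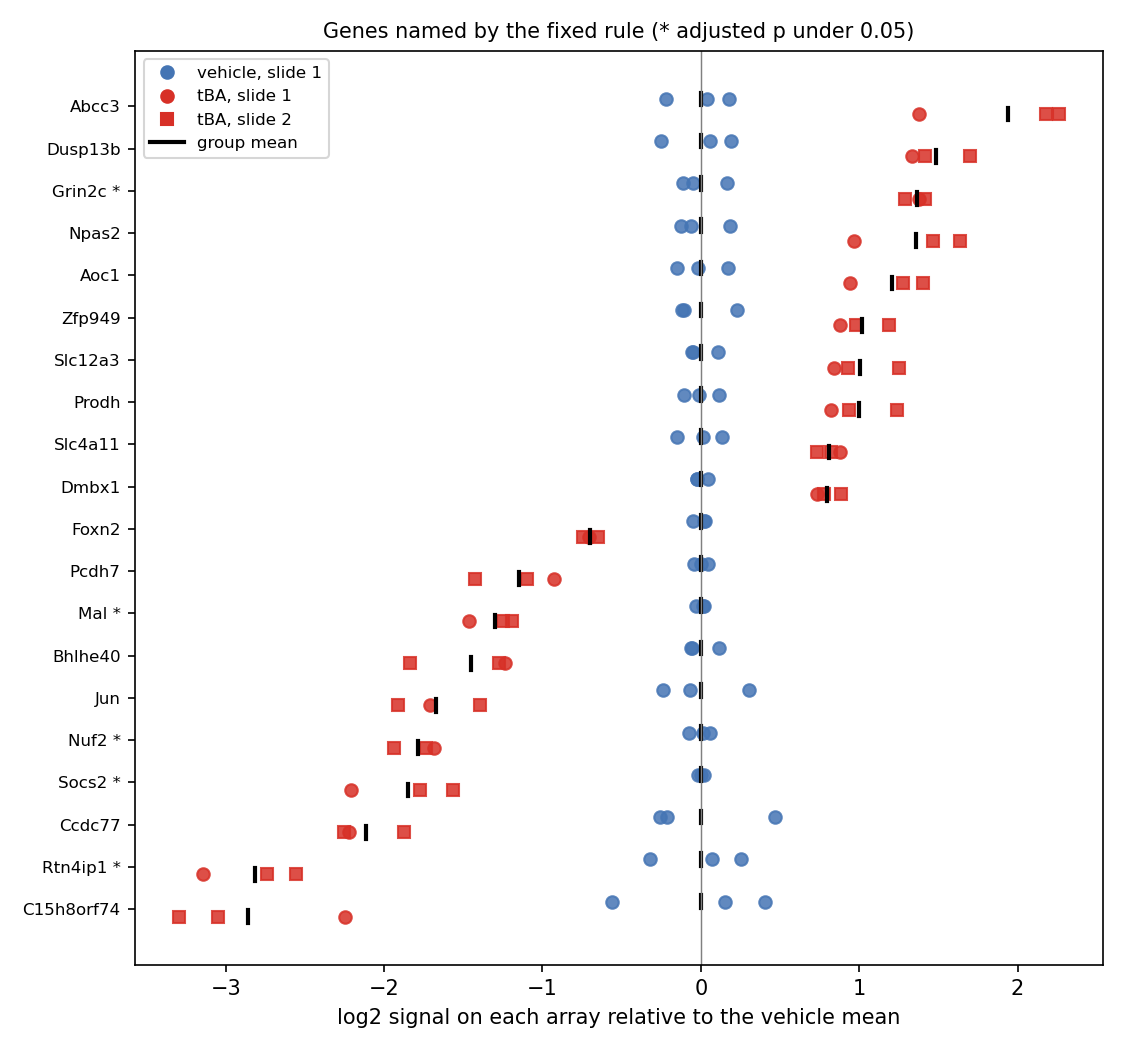
Log2 signal of the 20 genes of the naming rule on each of the 6 arrays, relative to the vehicle mean, with circles for slide 1, squares for slide 2 and bars for group means. Asterisks mark the 5 genes with an adjusted p under 0.05, and in Socs2 the tBA arrays of both slides lie below the 3 vehicle arrays.

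The sentinel genes, fixed in advance for nuclear receptor activation, lipid metabolism, stress and proliferation, gave 0 calls at an adjusted p of 0.05 in limma, and 5 of them had an unadjusted p under 0.05. The phenobarbital-inducible Cyp2b2 and Cyp2b1 were at 1.27 (SE 0.29, adjusted p = 0.199) and 0.90 (SE 0.18, adjusted p = 0.175) on the log2 scale. The sequences of these genes are near-identical, so their separate values are uncertain; with slide as a block Cyp2b1 was at 0.57. Cyp2e1, an ethanol-oxidising cytochrome P450, was at 0.69 (SE 0.13), Cyp3a23-3a1 at 0.66 (SE 0.14) and the haem oxygenase Hmox1 at -0.48 (SE 0.17). For these 5 genes, the ones under 0.05 unadjusted, the 3 tBA values lay outside the vehicle range, where the exact permutation test of 3 against 3 cannot go below p = 0.1. The 3 tBA values of Cdkn1a also lay outside it, at an unadjusted limma p of 0.365. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.37 (SE 0.69), with vehicle replicate 3 at -1.21 against 1.16 or higher in the other vehicle arrays. Cyp7a1 was at -0.86 without vehicle replicate 1 and at -2.21 without vehicle replicate 3. Fasn was at -0.64, at -0.38 without vehicle replicate 1 and at -0.14 with slide as a block; Cyp1a2 was at 0.24 and turned to -0.11 without vehicle replicate 3. Cdkn1a was at 0.089 by its brightest probe and at 1.19 or higher by the others, and turned to -0.018 under quantile normalization. Cyp2c11 at -0.31, Nqo1 at -0.70, Cyp4a1 at -0.008 and Gstp1 at 0.037 each changed sign under at least 1 alternative. Cyp1a1 was not well above background on any array, and no probe was named Mki67.

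Of 39 gene lists fixed before the data were examined, 8 passed camera, 6 higher and 2 lower with tBA; the other 9 splits of the 6 arrays into 3 and 3 gave 2 to 12 passing lists. Genes that respond to the nuclear receptors CAR and PXR rose as a group. Of 32 tested, 26 were higher with tBA and 6 lower, with a mean log2 difference of 0.51 and camera adjusted p of 4.06e-07 (adjusted p = 0.287 with an estimated correlation). Of these, 9 were higher when adjusted over the list alone and 0 passed over all genes. Examples were Abcc3 at 1.94, the carboxylesterase Ces2c at 1.52, Cyp2b1 at 0.90 and Cyp3a23-3a1 at 0.66, none passing over all genes. The glucuronosyltransferases and sulfotransferases, which conjugate drugs and hormones, rose too, with 16 of 20 higher, a mean of 0.57 and camera adjusted p of 0.00366 (adjusted p = 0.715 with an estimated correlation). For this list 7 were higher when adjusted over the list alone and 0 over all genes. Sult2a2 was at 2.14, well above background on 2 of 3 vehicle arrays, and Ugt1a1, Ugt1a6 and Ugt1a2 were at 0.79, 0.68 and 0.59. The Ugt1a genes share exons, so these values are not separate measurements, and 1 of the 3 probes of Ugt1a6 was lower. Sult2a2 was at 1.03 with normexp background correction, Ugt1a1 and Ugt1a2 at 0.41 and 0.35 with slide as a block, and Ugt1a6 at 0.39 by the mean of its probes. Within slide 1 and with slide as a block, which both rest on tBA replicate 1 alone, the means of both lists were 0.48 and 0.43. The call of the second list ended without vehicle replicate 2, at a mean of 0.33 (adjusted p = 0.0615), and within slide 1 (adjusted p = 0.122).

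Genes of cholesterol synthesis and uptake fell as a group. Of 25 tested, 21 were lower, with a mean of -0.68 and camera adjusted p of 3.13e-07 (adjusted p = 0.715 with an estimated correlation). In this list 9 were lower when adjusted over the list alone and 0 over all genes. Lanosterol synthase, Lss, was at -1.92 (SE 0.26), the mevalonate pathway enzyme Mvd at -0.97 (SE 0.14) and the sterol carrier Stard4 at -0.62 (SE 0.14), none passing over all genes. Vehicle arrays differed among themselves in this list, with means of 0.34, 0.091 and -0.43 relative to their average, against -0.53, -0.83 and -0.66 on the tBA arrays. Within slide 1 and with slide as a block, both from the same 1 tBA array, the shift was -0.53.

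Cell cycle genes fell as a group. Of 27 tested, 24 were lower, with a mean of -0.64 and camera adjusted p of 2.7e-10 (adjusted p = 0.715 with an estimated correlation). A total of 19 were lower when adjusted over the list alone and 0 over all genes. The cyclin of S-phase entry Ccne1 was at -1.21 (SE 0.17), the cytokinesis factor Prc1 at -0.98 (SE 0.18), the mitotic kinase Aurka at -0.62 (SE 0.09) and the transcription factor Foxm1 at -0.54 (SE 0.10). With normexp background correction Prc1 was at -0.39 and Foxm1 at -0.31, and with slide as a block Prc1 was at -0.56. Relative to the vehicle mean, tBA replicates 1, 2 and 3 were at -0.36, -0.86 and -0.70, and the vehicle arrays between -0.066 and 0.079. With slide as a block the shift was that of tBA replicate 1 alone, -0.36. With normexp background correction it was -0.38, with a camera adjusted p of 6.37e-11. Camera compares genes with genes at a preset correlation, so its p does not measure spread between animals. Alongside, the T and NK cell, B cell and macrophage marker lists had means of -0.24, -0.35 and -0.15, with camera adjusted p of 0.148, 0.148 and 0.159.

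Smaller shifts passed in 4 further lists. All 14 heat shock protein genes tested were higher, with a mean of 0.37 and camera adjusted p of 0.000223 (adjusted p = 0.715 with an estimated correlation). The co-chaperone Bag3, at 0.80 (SE 0.16), was the 1 gene that passed when adjusted over the list alone, and 0 passed over all genes; Hspb1 was at 0.53, Hspd1 at 0.40 and Dnaja1 at 0.39. Fatty acid oxidation genes that respond to PPARalpha had 29 of 35 higher and a mean of 0.33, with camera adjusted p of 0.000247 (adjusted p = 0.715 with an estimated correlation). In that list 0 passed when adjusted over the list alone or over all genes, with 8 at an unadjusted p under 0.05; Cpt1b and Crat, of the carnitine system, were at 0.95 and 0.91, and the hepatic hormone Fgf21 at -0.88. Respiratory chain genes had 36 of 40 higher at a mean of 0.13, with camera adjusted p of 0.000383 (adjusted p = 0.715 with an estimated correlation), and 0 passed when adjusted over the list alone, with 4, Uqcrq among them at 0.77, at an unadjusted p under 0.05. Urea cycle and amino acid catabolism genes had 21 of 25 higher at a mean of 0.16, with camera adjusted p of 0.00146 (adjusted p = 0.715 with an estimated correlation). Glutamine synthetase, Glul, went the other way at -1.06 (SE 0.19) and was the 1 gene of this list that passed when adjusted over the list alone, while Tdo2 was at 0.62, Glud1 at 0.51 and Arg1 at 0.34. With slide as a block, again on 1 tBA array, the PPARalpha and respiratory chain calls ended, at adjusted p of 0.627 and 0.995, with shifts of 0.12 and 0.017. The heat shock and urea cycle lists had shifts of 0.28 and 0.17 there. In single genes the block gave 0.15 for Hspd1, 0.25 for Dnaja1, 0.29 for Glud1 and 0.44 for Uqcrq, and Hspd1 was at 0.26 under quantile normalization. Quantile normalization ended the urea cycle and respiratory chain calls, at means of 0.070 and 0.034 (adjusted p = 0.101 and 0.455). The urea cycle mean was 0.25 without vehicle replicate 2 and 0.11 without vehicle replicate 3, and the PPARalpha mean 0.22 without tBA replicate 2, with the calls kept.

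**Figure D2:**
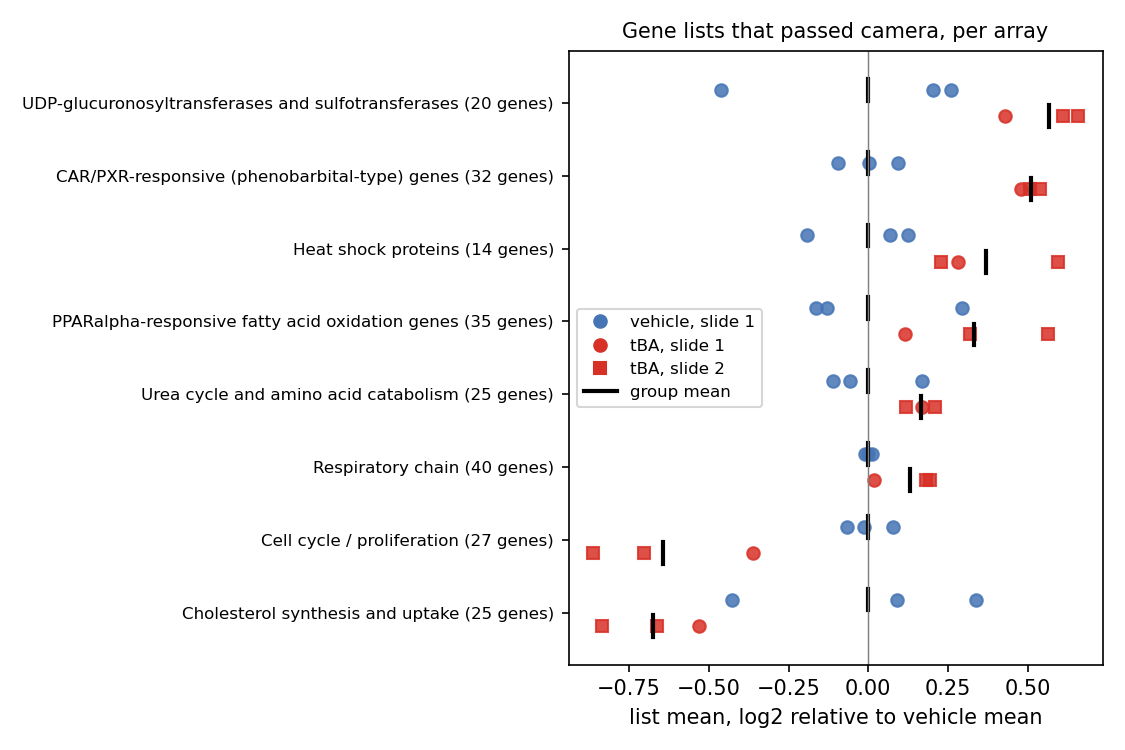
Mean log2 signal of the 8 gene lists that passed camera on each of the 6 arrays, relative to the vehicle mean, with circles for slide 1, squares for slide 2 and bars for group means. The tBA arrays lie below the vehicle arrays in the cell cycle and cholesterol lists and overlap them in the PPARalpha and urea cycle lists.

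Clock genes were higher and lower within 1 list. Of 17 tested, 4 were higher and 4 lower when adjusted over the list alone and 0 passed over all genes, and the list as a whole had a camera adjusted p of 0.26. The transcriptional activators Npas2 and Clock were at 1.36 (SE 0.19) and 0.50 (SE 0.10), while the output factor Dbp was at -2.53 (SE 0.35) and the repressor Bhlhe40 at -1.45 (SE 0.18). All 4 probes of Dbp and all 3 probes each of Npas2 and Clock had the same sign, though another probe of Npas2 was at 0.21 and the mean of its probes at 0.86. The fry mixed test, which asks whether genes of a list change in either direction, gave an adjusted p of 0.00638 here and passed 16 of the 39 lists, the hepatocyte markers (adjusted p = 0.0374) among them.

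In the list of male-biased, growth-hormone-dependent genes, 7 of 19 were higher and 12 lower, with a median of -0.072; 3 were lower when adjusted over the list alone, and 1, Socs2, also passed over all genes. Cish, another inhibitor of cytokine receptors, was at -2.39 (SE 0.58), Igfals, which carries insulin-like growth factors in serum, at -0.64 (SE 0.14) and Mup4 at -0.31 (SE 0.11). The camera adjusted p of this list was 0.26 and its fry mixed adjusted p 8.38e-05, in a test that passed 16 of 39 lists.

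Marker lists of other cell types did not pass camera. Hepatocyte markers had a mean of -0.021 (adjusted p = 0.979), and bile duct, stellate, endothelial, neutrophil and red blood cell markers had means of 0.041, -0.074, 0.10, 0.062 and -0.074. Pancreatic, muscle and adipocyte markers, which would show admixed tissue, had means of 0.19, 0.091 and 0.17. These means hide differences between arrays. On tBA replicates 1, 2 and 3 the muscle markers were at -0.57, 0.37 and 0.48. In the same order the pancreatic markers were at 0.038, -0.0027 and 0.54 and the adipocyte markers at -0.16, 0.58 and 0.094. Of the function lists, glucose metabolism was at 0.26 (adjusted p = 0.0999), interferon genes at -0.21, lipogenesis at -0.25, NRF2 genes at 0.086, AhR genes at 0.15, p53 genes at -0.031, endoplasmic reticulum stress genes at -0.098, acute phase genes at 0.067, glutathione transferases at 0.021, thyroid-related genes at 0.060, periportal genes at 0.15, female-biased genes at -0.18 and preneoplastic markers at -0.085. None of these lists passed.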

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

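The within-slide test of the gene lists was chosen after seeing the data, and the other alternatives before. Against 43 probes and 5 genes, a floor on dim signals gave 70 and 9, an intensity trend in eBayes 68 and 12, no filter on dim probes 18 and 1, and slide as a fixed block 20 and 2; probes above background on all 6 arrays gave 0 and 0 in limma (5637 and 1634 at an unadjusted p under 0.05), as did slide 1 alone (2956 and 806). An adjusted p under 0.10 gave 120 probes and 27 genes. The other scalings, the authors' table, a 1.5-fold minimum and slide as a random block stayed within 1.5 times, and the median difference of all probes, 0.015, was at most 0.088. The random block estimated a correlation within slides of 0.0076, so it was nearly the main fit and says little about slide. Like counts can hide other probes: with normexp background correction 57 probes and 7 genes passed, of which 28 and 3 were among the 43 and the 5. Without tBA replicate 1, 22 of the 45 probes were among the 43. The remaining scalings, the authors' table and the random block kept 40 to 42 of the 43. Under quantile normalization 2 of 6 genes were higher, against 1 of 5. Leaving out 1 array gave 6 to 45 probes and 0 to 9 genes: 6 and 0 without tBA replicate 2, 14 and 1 without tBA replicate 3, 22 and 2 without vehicle replicate 1, 25 and 3 without vehicle replicate 3, and 9 genes without tBA replicate 1. The run with 0 genes had 1097 at an unadjusted p under 0.05. Filtering to all 6 arrays takes out by construction the 25 of the 43 probes that were dim in 1 group. Rtn4ip1, Socs2 and Grin2c kept their log2 differences of -2.81, -1.85 and 1.36 there, so their calls depended on which other probes were tested. The cause of the other differences was not tested, except that slide 1 alone and the left-out arrays leave fewer samples. The sentinel genes gave 0 calls throughout.

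The replicate numbers showed no sign of pairing the animals: the same-number correlations of deviations were -0.0562, -0.0642 and 0.0143, against -0.0576 to 0.113 for other pairs. Taken from group means of 3 arrays, these correlations cannot exclude a pairing. With the replicate block 6 probes and 0 genes passed (1336 genes at an unadjusted p under 0.05), with fewer residual degrees of freedom, and 9 lists.

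Of 8 lists that passed camera, 0 passed camera with an estimated correlation (2 of 39 lists at an unadjusted p under 0.05) and 1, the CAR and PXR list, with fry. All 9 lists followed kept their direction, and leaving out 1 array gave 7 to 10 passing lists. Among 79 named genes under all alternatives, 18 of 1575 values changed sign, in 6 sentinel genes that did not pass: with slide as a fixed block and within slide 1, Cyp2c11 was at 0.093 and Nqo1 at 0.50; under quantile normalization Cdkn1a was at -0.018 and Gstp1 at -0.017; with median centring Cyp4a1 was at 0.065; and with the mean of all probes Gstp1 was at -0.072. Leaving out 1 array gave ranges of -0.51 to 0.021 for Cyp2c11, -0.27 to 0.25 for Cyp4a1, -0.11 to 0.46 for Cyp1a2, -0.018 to 0.14 for Gstp1 and -1.30 to 0.088 for Nqo1. Signal over background limited 25 of the 43 probes, which were dim in 1 group.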

Other observations

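Further lists had members that passed when adjusted over the list alone, though none passed camera. In the iron and metal list, with a mean of 0.28, a median of 0.075 and 11 of 12 genes higher, the transferrin receptor Tfrc was at 0.59 (SE 0.13) and passed over the list alone, and the iron hormone Hamp was at 2.15 (SE 0.57) without passing. In the bile acid list, with a mean of -0.043, a median of 0.18 and 10 of 18 genes higher, Akr1d1 and Cyp27a1 were at 0.62 (SE 0.09) and 0.63 (SE 0.14) and passed over the list alone, while Slc27a5 was at 0.70 and the sterol exporter Abcg5 at -0.70. In the pericentral list, with a mean of 0.021, Cyp2e1 was at 0.69 and Glul at -1.06, both passing over the list alone and in opposite directions. In the alcohol oxidation list, with a mean of 0.13, Cyp2e1 was the 1 gene that passed over the list alone, and Aldh1a1 at 0.86 and Cat at -0.52 did not pass. The 1 gene that passed over the list alone was Ugt1a6 at 0.68 (SE 0.10) in the AhR list, the fatty acid desaturase Fads1 at -1.60 (SE 0.31) in the lipogenesis list and Fcnb at -0.64 (SE 0.17) among the neutrophil markers. No gene of these 7 lists passed over all genes.

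Of the tests below, those of the count of probes, genes and lists over the splits and of the trend with signal level were planned before their results were seen; the others were chosen after. The real split called 43 probes against at most 3 in the other splits, and 5 genes against at most 1, and 1 of the 10 splits, the real one, reached each count. With 10 splits no share under 0.05 can be had. For the lists the real split called 8, and 5 of the 10 splits called as many or more, the highest other 12, so the number of passing lists does not set the real groups apart. The means per array did not overlap between the groups in 10 of the 39 lists, against 10% by chance. This share is near the 24.1% of single genes whose groups did not overlap, so it does not set the lists apart.

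A set of 31 probes had signal on all arrays of 1 group and none of the other, with a gap of over 2 on the log2 scale: 20 with tBA and 11 with vehicle. Of the 31, 22 were among the 43 probes that passed, so the counts of both sets over the splits are not separate evidence. None of the 20, which carry 16 different accessions, could be named. Against the background limit of each array, probe A_44_P422152 was at least 20.4-fold higher and A_64_P012471 at least 17.7-fold higher. Both bounds are lower with 1 floor for all arrays, at -5.20 against tBA means of -1.03 and -1.24. Splits that mix the groups held at most 4 such probes, which argues against independent variants carried by single animals; 1 of 10 splits, the real one, reached 31. The median shift on the tBA array of slide 1 was 98.0% of that on slide 2. The selection asked for signal on that array too, so this value cannot decide on a difference between slides. Such a difference alone would not set tBA replicate 1 apart from the vehicle arrays of its slide. Splits that joined both slide 2 arrays with 1 vehicle array held 0 such probes, against 31 in the real split. Slide 1 held only 1 tBA array, so these counts rest on that array and do not decide on a slide difference. A single transcript, linked locus or shared response to tBA remains possible and was not tested.

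The clock genes may reflect a shift of phase. Of 17 tested clock genes, 13 were placed in 2 arms after their values were seen and 4 in none, so the arms describe the pattern and do not test it. Relative to vehicle, 5 of 5 activator-phase genes were higher and 7 of 8 output genes lower, and the activator minus output difference was 1.85 ± 0.58 (SD, n = 3 arrays) with tBA against a vehicle SD of 0.37. The tBA array of slide 1 was at 1.19, but as this is 1 array a difference between slides stays open. Another time of day at sampling and a phase shift by the compound cannot be told apart, since the labels do not give the sampling hour. That missing hour also limits the other differences between tBA and vehicle, and its part in them was not tested.

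For the lower cell cycle genes, the trend with signal level was weighed by random lists matched on mean signal: 0% of 10000 had a median as low as -0.54, the lowest being -0.40. An even loss of immune cells would lower their markers as much. These had a median of -0.23 (SE 0.053 over genes) in 28 genes, and the cell cycle median had an SE of 0.12. On tBA replicate 1 the T and NK cell, B cell and macrophage means were -0.30, -0.28 and -0.18. The cell cycle mean there was -0.36. On replicate 2 the 3 marker means were -0.43, -0.81 and -0.21, against -0.86. On replicate 3 they were 0.0034, 0.034 and -0.074, against -0.70. The arrays differ and neither SE measures spread between animals, so the medians do not decide on an even loss. The markers also cannot exclude a loss mainly of dividing immune cells. On the tBA array of slide 1 the cell cycle list mean of -0.36 stood against a vehicle SD of 0.073. As this is 1 array, a difference between slides stays open. Lower proliferation of liver cells after dosing is a candidate explanation that these tests leave open, and the tBA group also differs in slide.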
